A study of Mus musculus with 4 samples.

How the data were processed

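Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in nuclei of whole hearts of newborn C57BL/6 mice (postnatal day 0). There were 4 libraries, 2 from wild-type (WT) hearts and 2 from hearts labelled edKO, which per the labels' protocols lacked both RXR alpha and RXR beta in cardiomyocytes. Per the series' design text each library came from 1 heart, so the 2 libraries of a group are biological replicates. Groups and replicate numbers were taken from the sample titles. The sex of the hearts is not labelled.

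The authors deposited 1 peak list per library, so peaks were called per sample and replicates were not pooled. Per the submitters' processing notes the tools were CASAVA, bcl2fastq, cutadapt, Bowtie2, SAMtools and MACS2, with the builds mm10 and GRCm38. Their versions, the shift applied for the Tn5 insertion, the treatment of duplicates and mitochondrial reads, and any filter on regions are not given in the sources used here. For each peak the authors' deposited lists give the fold enrichment at the summit (a ratio of pileup to local background within the same library), the −log10 p and the −log10 q-value of that summit, the position of the summit in bases from the start of the peak, and a score. The authors' score was the whole part of 10 times the −log10 p in at least 99.98% of the peaks of each list and was used in no test. The lowest −log10 p was 3.02, 3.02, 3.00 and 3.04 in WT 1, WT 2, edKO 1 and edKO 2. The deposited lists hold peaks on chromosomes 1 to 19 and X only, with 0 peaks on the Y chromosome. These fold and −log10 p values are the authors' and served to describe, rank or filter peaks within a list. Summed up over a whole list, they also served to compare depth and enrichment between libraries. They scale with depth and background, so at a single region they do not measure a difference between libraries.

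Depth was read from the lists themselves. The authors' fold and −log10 p of a peak were solved together for the pileup and the local background under a Poisson tail, which gave a whole-number pileup, within 0.001 in −log10 p, for 99.9858% to 100% of the peaks of a list. The lowest background of a library then stands for its relative depth. It was 1.81 in WT 1, 1.80 in WT 2, 1.51 in edKO 1 and 1.92 in edKO 2, and the median pileup at a summit was 23, 23, 19 and 18. A weak site passes the authors' threshold more easily in a deeper library or in one with a higher share of fragments in open chromatin, so a missing call means that the site stayed below the threshold in that library, not that it was closed.

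Peaks of all 4 libraries that overlapped by at least 1 bp were merged into 53140 regions, and a library counted as called in a region if any of its peaks overlapped it by at least 1 bp. WT-only regions were called in both WT libraries and in neither edKO library, and edKO-only regions the reverse. The same count was made for the 4 pairs of 1 WT and 1 edKO library. With 2 libraries against 2 there are 3 splits, and an exact permutation test cannot give a two-sided p below 0.333. The strength of a region was the mean, over both libraries of the group, of the percentile of its −log10 p within each list. Region classes and gene lists were compared by an exact conditional Mantel-Haenszel test, two-sided, over 10 strata of strength, with the regions called in both libraries of the group as background. Odds ratios have 95% intervals, and p-values were adjusted by the Benjamini-Hochberg method over the 16 lists within each direction. Lists were tested at gene ends by Fisher's exact test, two-sided. Regions are not replicates, so these p-values compare the 4 libraries and not the genotypes. On simulated data, with 100 list regions among 28087, true odds ratios of 1, 1.5 and 2.5 were recovered as means of 1.00, 1.44 and 2.57 over 200 simulations. They gave a p below 0.05 in 4.5%, 21.5% and 90.5% of simulations. The simulated list regions were drawn singly and independently, so these shares do not cover lists in which several regions belong to the same gene.

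Gene positions came from a RefSeq gene table of the same build, GRCm38.p6, which holds 21631 protein-coding genes with start and end but no strand and no exons. Therefore 3 steps planned with transcription start sites were run with gene ends. A region was assigned to the protein-coding gene with the nearest end, start or stop, within 100 kb, which gave a gene to 47920 regions (90.2%). Regions within 1 kb of either end of a gene were classed as gene end, other regions over a gene as gene body, without exons and introns being told apart, and the remainder as intergenic. The planned tests of 23 sequence motifs needed genome sequence and are not analysed here, nor is the GC content of the regions. Nearest-gene assignment does not show which gene a region acts on.

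The 16 lists held 413 genes, all matched in the gene table: fatty acid uptake and oxidation, PPAR and RXR target genes, oxidative phosphorylation and TCA cycle, glycolysis and glucose uptake, sarcomere and excitation-contraction coupling, cardiac transcription factors, nuclear receptors, cell cycle, housekeeping, and markers of endothelial and endocardial, fibroblast, smooth muscle and pericyte, epicardial, immune, erythroid, and neuronal and Schwann cells. Lists, tests, named-gene rule and most alternatives were fixed before the data were examined. The named genes are Rxra, Rxrb and Rxrg, the genes nearest to the 10 strongest WT-only and the 10 strongest edKO-only regions, the 5 genes with the most such regions in each direction, up to 3 members of each list with the strongest such region, and list members whose gene end was WT-only or edKO-only. One gene that the rule names is not reported here. Ppargc1b, Rarb, Abcg1, Txnip, Ucp3, Abca1, Dhrs3, Klf15, Srebf1, Myl7, Tubb3 and the strong regions beyond the first 10 were named after their values had been seen. Alternatives were a stricter threshold (−log10 p of at least 10) in every list or in the group holding the call only, lists reduced to the length of the shortest, calls requiring that peaks cover at least 50% of a region, windows of 100 bp on each side of the summits, a gene-end window of 2.5 kb, gene bodies with 10 kb on each side, 10000 random gene lists, no strata, chromosomes 1 to 19 only, and each library left out in turn. After the data had been seen, strata by region class, lists without shared members or without the member with most WT-only regions, random lists that take strength into account, and the removal of regions within 2 Mb of Rxra and Rxrb were added. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.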

Results

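Open chromatin was profiled by ATAC-seq in 4 newborn mouse hearts to ask which accessible regions of the perinatal heart depend on the retinoid X receptors RXR alpha and RXR beta, nuclear receptors that pair with PPAR, LXR, retinoic acid and thyroid hormone receptors on DNA. WT hearts (n = 2) were compared with hearts labelled edKO (n = 2), in which both receptors were deleted in cardiomyocytes. Peaks were called by the authors in each library on its own, and coordinates are those of GRCm38.

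Both targeted genes carried called regions in all 4 libraries, and each held 1 region that was called in both WT hearts and in neither edKO heart. Rxra (chromosome 2, 27676445 to 27763319) overlapped 7 merged regions, of which 6 and 7 were called in WT 1 and WT 2 and 5 in each edKO library. Its WT-only region lay in the gene body (27679692 to 27680039), with the authors' −log10 p at 15.5 in WT 1 and 18.7 in WT 2. Rxrb (chromosome 17, 34031812 to 34038403) overlapped 2 regions. The one at its gene end (34031367 to 34032464) was called in all 4 libraries, and the one in its body (34034095 to 34034339) was WT-only, at −log10 p of 10.5 and 8.58. Rxrg, the third receptor of the family and not targeted, overlapped 2 regions, called in 0, 1, 1 and 0 of WT 1, WT 2, edKO 1 and edKO 2. The deleted exons were not located here, so these calls do not check the genotype labels.

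Fewer peaks were called in the edKO hearts, at 27307.5 ± 234 (SD, n = 2), than in the WT hearts, at 37044 ± 2496 (SD, n = 2), a ratio of 0.737. The libraries held 35279 (WT 1), 38809 (WT 2), 27473 (edKO 1) and 27142 (edKO 2) peaks, with median widths of 344, 344, 335 and 322 bp. The exact permutation test gave p = 0.333, the smallest p that 2 hearts against 2 allow. Both edKO libraries also stood apart from the WT libraries in technical measures, each in its own way. The background level, taken here to stand for depth, was 1.81 and 1.80 in WT 1 and WT 2, 1.51 in edKO 1 and 1.92 in edKO 2. The median fold enrichment of the 10000 strongest peaks was 10.8 and 11.5 in WT 1 and WT 2, 10.2 in edKO 1 and 7.61 in edKO 2.

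**Figure D1:**
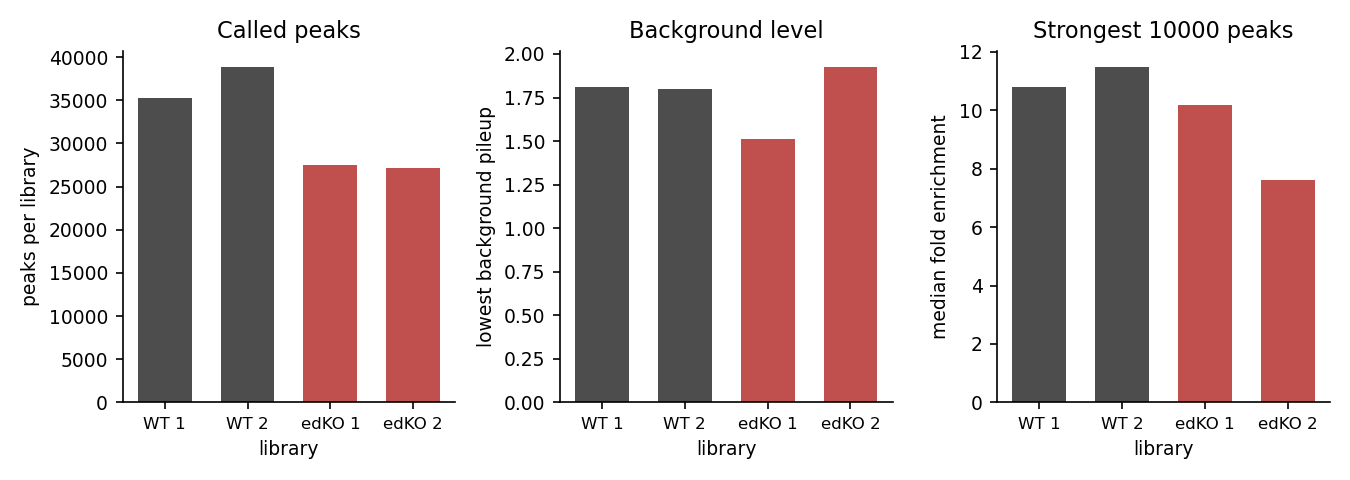
Bars give, for each of the 4 libraries (WT grey, edKO red), the number of called peaks, the lowest background pileup and the median fold enrichment of the 10000 strongest peaks. Both edKO libraries had fewer peaks, edKO 1 had the lowest background (1.51) and edKO 2 the lowest fold enrichment (7.61).

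The peak lists of the WT hearts shared 59.8% of their covered bases (Jaccard index). The edKO hearts shared 49.0% with each other, within the range of the 4 pairs of different genotype, 44.0% to 53.9% with a mean of 48.9%. Of the 53140 merged regions, 16568 were called in all 4 libraries.

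The strongest regions called in both WT hearts and in neither edKO heart (WT-only) belonged to Pdk4 and Angptl4, both on the list of PPAR and RXR target genes. The first lay 12952 bp from Pdk4, which encodes a kinase that shuts off pyruvate dehydrogenase and so spares glucose when fatty acids are burned (chromosome 6, 5509230 to 5510367, intergenic). The next lay inside Angptl4, which encodes a secreted inhibitor of lipoprotein lipase (chromosome 17, 33778968 to 33779986), and within 2 Mb of the targeted gene Rxrb. The authors' −log10 p was 91.4 in WT 1 and 103 in WT 2 at the Pdk4 region, with fold enrichments of 13.4 and 16.3, and 79.4 and 103 at the Angptl4 region, with fold enrichments of 8.38 and 10.2. The gene end of Pdk4 itself (5495969 to 5496915) was called in all 4 libraries. That of Angptl4 (33781130 to 33781508) was called in both WT hearts and in edKO 1.

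**Figure D2:**
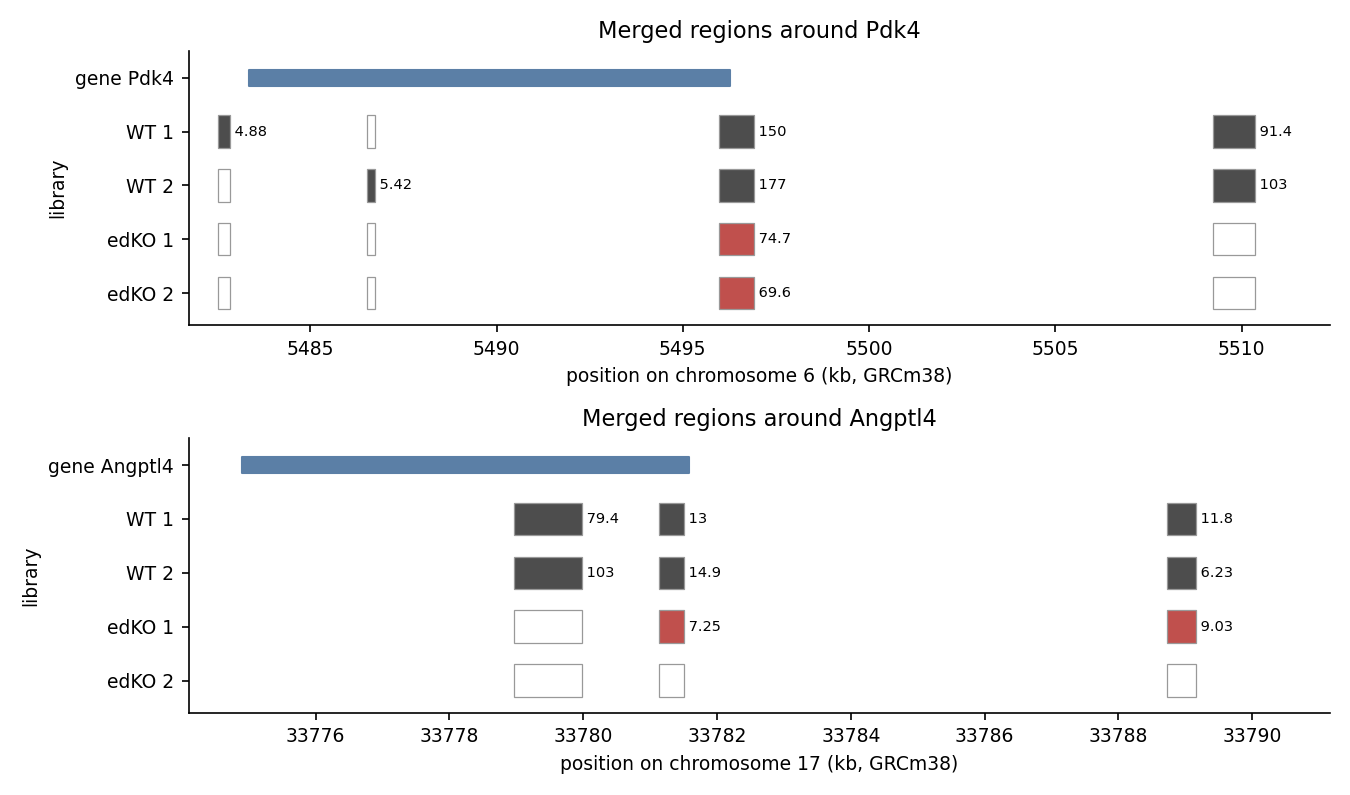
Merged regions around Pdk4 (chromosome 6) and Angptl4 (chromosome 17) are drawn to scale along the chromosome in kb, filled where a library was called and open where it was not, with the authors' −log10 p beside each filled box. The region 12952 bp from Pdk4 and the region inside Angptl4 were called in both WT libraries and in neither edKO library, while the Pdk4 gene end was called in all 4.

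The remaining 8 of the 10 strongest WT-only regions included sites 5368 bp from Acot2, a mitochondrial acyl-CoA thioesterase (chromosome 12, 83999245 to 83999850), and inside Crat, the carnitine acetyltransferase (chromosome 2, 30409459 to 30409945). Others lay inside Nrip1, which encodes a corepressor of nuclear receptors (chromosome 16, 76293695 to 76294293), and inside Adra1b, an adrenergic receptor (chromosome 11, 43820678 to 43821577). A further site was 9604 bp from Impa2, an inositol monophosphatase (chromosome 18, 67279119 to 67279643). Sites 42548 bp from Cd28 and 50071 bp from 4930519L02Rik, and 1 with no gene end within 100 kb (chromosome 1, 42532901 to 42533329), completed them. By number, Impa2, Klhl3 and Rad51b each had 6 WT-only regions, of 9, 10 and 14 assigned to them and called in both WT hearts, and 2900026A02Rik (of 13) and Abca4 (of 11) had 5 each.

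In all, 28087 regions were called in both WT hearts, of which 5440 (19.4%) were WT-only and 6079 were called in 1 edKO heart. The reverse was much rarer, with 236 edKO-only regions among the 17442 called in both edKO hearts (1.35%). Pairs of 1 WT and 1 edKO heart held 491 to 1259 regions that the remaining pair lacked. Most WT-only regions were weak, with a median strength at the 31.9th percentile against 60.1 for all regions called in both WT hearts. Above the 75th percentile 35 of 8985 were WT-only, whereas no edKO-only region and no region of a mixed pair lay there. Every pair other than the WT pair was set against at least 1 WT library, with its longer peak list. This contrast therefore does not separate genotype from the sensitivity of the libraries. With every list reduced to the length of the shortest, the count was 2324 WT-only regions against 670 edKO-only regions and at most 1105 in a mixed pair, and with −log10 p of at least 10 required in the WT hearts it was 914. Leaving out 1 heart asks for fewer libraries and gave 13077 (without WT 1), 10549 (without WT 2) and 10087 (without edKO 1), and the 3 splits of the 4 libraries allow no p below 0.333.

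**Figure D3:**
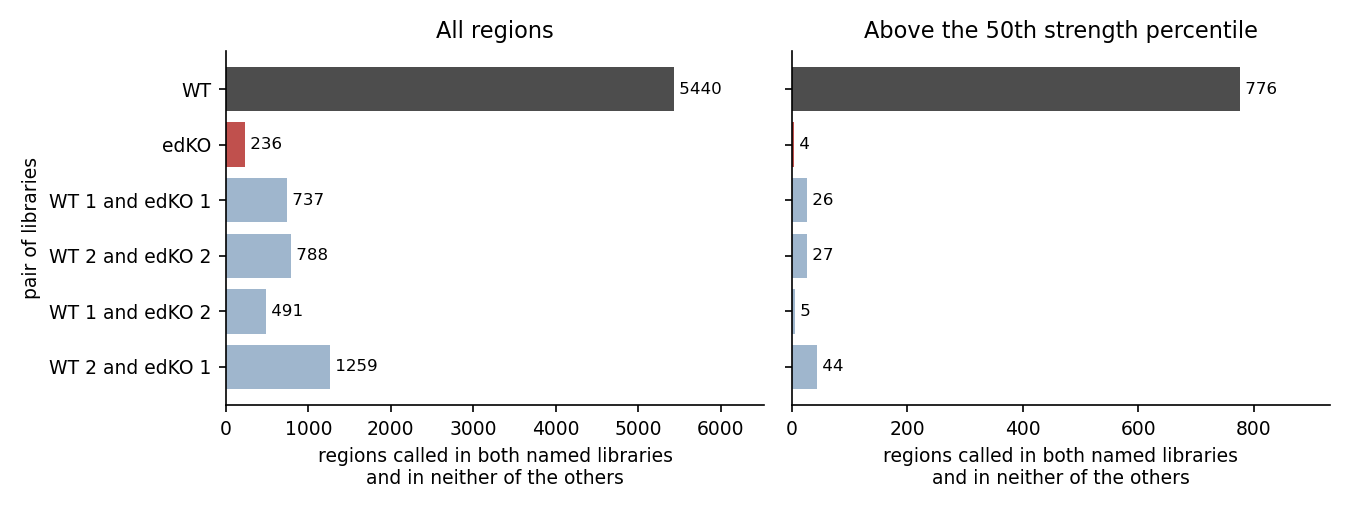
Bars give the number of regions called in both libraries of a pair and in neither of the remaining libraries, for the WT pair (grey), the edKO pair (red) and the 4 mixed pairs (blue), over all regions (left) and over those above the 50th strength percentile (right). The WT pair held 5440 such regions, 776 of them above the 50th percentile, against at most 1259 and 44 in a mixed pair.

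Regions of fatty acid uptake and oxidation genes were WT-only more often than regions of other genes at like strength. Of the 111 regions assigned to this list and called in both WT hearts, 28 (25.2%) were WT-only where 15.3 were expected from their strength, an odds ratio of 2.54 (95% interval 1.52 to 4.24, adjusted p = 0.00202 by the exact Mantel-Haenszel test with Benjamini-Hochberg adjustment). They were spread over 19 of the list's 40 genes. Besides Acot2, the strongest were in Cd36, which encodes the fatty acid transporter of the cell surface (chromosome 5, 17880789 to 17881221), at −log10 p of 44.8 in WT 1 and 30.7 in WT 2, and 4369 bp from Acaa2, the thiolase of mitochondrial beta oxidation (chromosome 18, 74810576 to 74811321), at 32.0 and 35.5. Cd36 had 3 WT-only regions among 9, and Ppargc1b, a coactivator of mitochondrial biogenesis named after its values had been seen, 3 of 10.

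Target genes of PPAR and other RXR partners showed a similar share. Of their 79 regions, 24 (30.4%) were WT-only where 14.3 were expected, an odds ratio of 2.31 (1.32 to 4.05, adjusted p = 0.0172 by the same exact test), in 13 of 28 genes. After Pdk4 and Angptl4 the strongest was a region 2883 bp from Acot1, the cytosolic acyl-CoA thioesterase (chromosome 12, 84020553 to 84020941), at −log10 p of 24.8 in WT 1 and 42.4 in WT 2. Of members named after their values had been seen, Rarb, a retinoic acid receptor, had 3 WT-only regions of 4, Abcg1, a sterol exporter, 3 of 5, Txnip, which restrains glucose uptake, 2 of 4, and Ucp3, a mitochondrial uncoupling protein, 1 of 1, while shares were lower in Abca1, another sterol exporter (3 of 9), Dhrs3 (2 of 9), Klf15 (1 of 7) and Srebf1 (1 of 4). Both lists share 4 members. In the edKO direction 0 of 60 fatty acid regions and 0 of 37 PPAR and RXR target regions were edKO-only where 0.533 and 0.446 were expected, too few to tell a difference. In the mixed pairs WT 1 and edKO 1, WT 2 and edKO 2, WT 1 and edKO 2, and WT 2 and edKO 1 the odds ratio of the fatty acid list was 1.01, 0.426, 0.746 and 0.299, and that of the PPAR and RXR list 1.74 (interval 0.503 to 6.02), 0.487, 0 and 1.01. These rest on only 2, 1, 1 and 1 fatty acid regions and 3, 1, 0 and 3 PPAR and RXR target regions. The intervals of the fatty acid list were 0.219 to 4.68, 0.0506 to 3.58, 0.101 to 5.49 and 0.0411 to 2.17. The mixed pairs therefore held too few regions to show that the excess is particular to the WT pair.

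Both results rest on comparing regions of like strength. Without strata the odds ratios were 1.51 (adjusted p = 0.164, Fisher's exact test) and 1.96 (adjusted p = 0.131) for the fatty acid and PPAR lists. In a permutation test against random gene lists matched on the number of regions alone, the ratios of observed to random WT-only regions were 1.16 (adjusted p = 0.838) and 1.42 (adjusted p = 0.310), and with the strength of each region taken into account the ratios to the expected number were 1.83 (adjusted p = 0.0288) and 1.68 (adjusted p = 0.0672). In the exact test the PPAR list also lost its call without WT 1 (odds ratio 1.55, adjusted p = 0.552), without WT 2 (1.68, adjusted p = 0.216) and without the shared members (1.95, adjusted p = 0.183). With lists of equal length the odds ratios rose to 4.97 and 3.59, with −log10 p of at least 10 in the WT hearts to 6.12 and 4.58, and with that threshold in every list to 3.57 and 5.20.

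**Figure D4:**
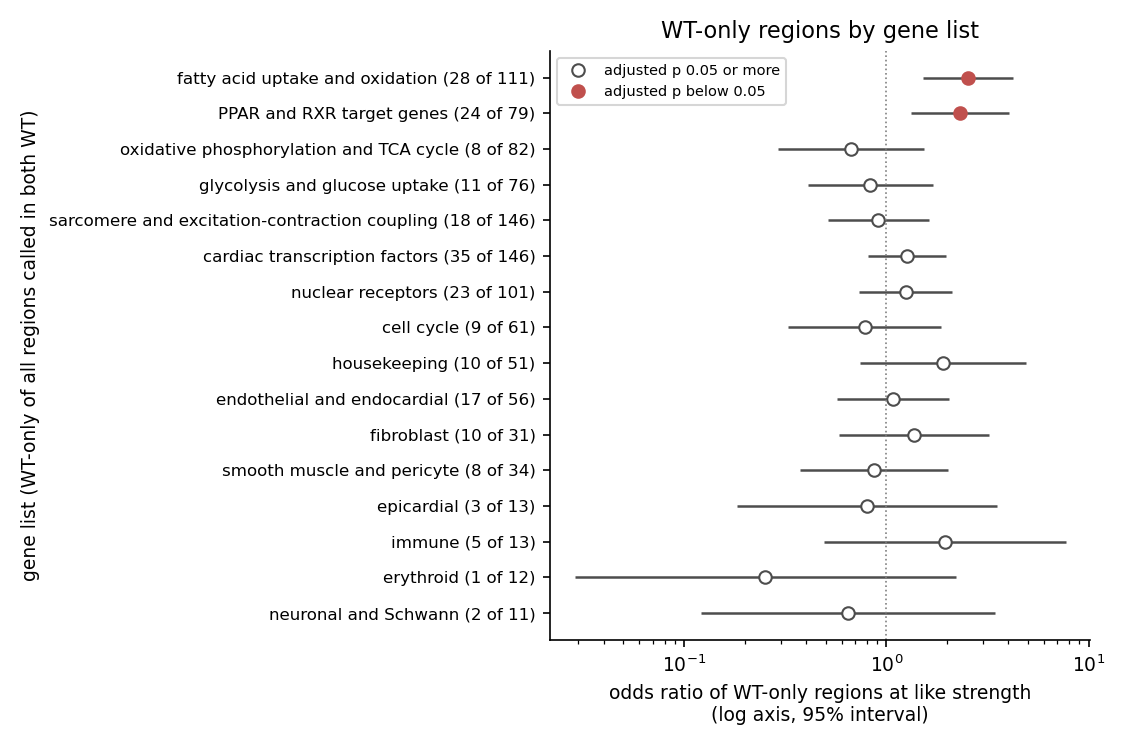
Points give the odds ratio of WT-only regions for each of the 16 gene lists at like strength, on a log axis with 95% intervals, and the labels give WT-only regions of all regions called in both WT hearts. Fatty acid uptake and oxidation (2.54) and PPAR and RXR target genes (2.31) lay above 1 with an adjusted p below 0.05, and the other 14 lists did not pass.

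The contractile, mitochondrial and glycolytic lists did not pass the test. Sarcomere and excitation-contraction genes had 18 WT-only regions of 146 (odds ratio 0.913, 0.514 to 1.62), the strongest near Myl4, the atrial light chain of myosin, inside Myom1 and at the gene end of Actc1, the cardiac actin. Oxidative phosphorylation and TCA cycle genes had 8 of 82 (0.669, 0.292 to 1.53), led by regions near Sucla2, Uqcrc1 and Esrrg. Glycolysis genes had 11 of 76 (0.832, 0.407 to 1.70), with the strongest inside Hk2, Pfkfb2 and Pfkfb3. Set directly against each other in 4 exact tests, fatty acid regions were WT-only more often than sarcomere regions (odds ratio 2.42, 1.15 to 5.10, adjusted p = 0.0409), oxidative phosphorylation regions (2.88, adjusted p = 0.0409) and glycolysis regions (2.48, adjusted p = 0.0456), and PPAR and RXR target regions more often than sarcomere regions (2.28, adjusted p = 0.0409). These tests were added after the data had been seen, and the lists used for comparison all had odds ratios below 1. The housekeeping list (odds ratio 1.90, 0.737 to 4.91) was not compared directly. Its interval includes the 2.54 of the fatty acid list, so these tests do not set that list apart from housekeeping genes.

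Regulators and markers of other cell types did not pass either. Cardiac transcription factors had 35 WT-only regions of 146 (odds ratio 1.26), the strongest near Gata4 and Irx3 and inside Mef2d. Nuclear receptor genes had 23 of 101 (1.24), led by Rxra, Nr1h2, which encodes LXR beta, and Vdr, the vitamin D receptor. Cell cycle genes had 9 of 61 (0.780), near Cdk1 and Ccnd1 and inside Ccnd3, and housekeeping genes 10 of 51 (1.90), near Eef1a1, Eef2 and Reep5. Endothelial and endocardial markers had 17 of 56 (1.08; Egfl7, Pecam1, Icam2), fibroblast markers 10 of 31 (1.37; Lamc1, Loxl1, Gsn), and smooth muscle and pericyte markers 8 of 34 (0.867; Mylk, Cspg4, Des). Epicardial (3 of 13; Wt1, Tbx18), immune (5 of 13; Spi1, Vav1, C1qa), erythroid (1 of 12; Ank1) and neuronal and Schwann markers (2 of 11; Th, Ngfr) held too few regions for a narrow interval. The lowest adjusted p among these 14 lists was 0.884.

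WT-only regions lay away from gene ends. Of the 10895 gene-end regions called in both WT hearts 645 (5.92%) were WT-only, against 2718 of 10085 in gene bodies (27.0%) and 2077 of 7107 between genes (29.2%). At like strength the odds ratio was 0.384 for gene ends (0.348 to 0.424, p = 4.4e-89, exact Mantel-Haenszel test), 1.30 for gene bodies (1.22 to 1.40) and 1.38 for intergenic regions (1.28 to 1.49). The gene-end odds ratio was 0.163 without strata. Regions of the mixed pairs with edKO 1 lacked a call in edKO 2. Their gene-end odds ratio was 0.490 with WT 1 (p = 6.21e-11) and 0.613 with WT 2 (p = 4.20e-09, same exact test). In the mixed pairs with edKO 2 no difference was detected, at 0.886 with WT 2 (p = 0.192) and 0.969 with WT 1 (p = 0.827, same exact test). For WT-only regions it was 0.276 without edKO 1 and 0.493 without edKO 2. How far the depletion at gene ends follows the low enrichment of edKO 2 was not tested.

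At the level of genes, 378 of the 11302 genes with a gene-end peak in both WT hearts had none in either edKO heart (3.34%), and 49 of 10300 the reverse (0.476%). The WT-only gene ends included Acot1 and Cd36 of fatty acid metabolism, Esrrg, which encodes an estrogen-related receptor of oxidative metabolism, Idh2, an isocitrate dehydrogenase, Thrb, a thyroid hormone receptor, the endothelial genes Plvap and Sox18, the fibroblast factor Tcf21 and the myeloid factor Spi1. The fatty acid list had an adjusted p of 0.532 (Fisher's exact test), and no list passed in either direction. Without edKO 2 the neuronal and Schwann list passed among edKO-only gene ends with 2 of 5 genes, Foxd3 and Tubb3 (adjusted p = 0.0323, Fisher's exact test). The excess of WT-only gene ends depended on the length of the lists: with lists of equal length 150 were WT-only and 156 edKO-only. With −log10 p of at least 10 in every list they were 690 and 9, and without WT 1, WT 2, edKO 1 and edKO 2 in turn 704, 589, 864 and 694 were WT-only and 84, 143, 426 and 160 edKO-only.

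Regions called in the edKO hearts alone were few and weak. The strongest of the 236 edKO-only regions lay at the gene end of Gadd45b, a stress-inducible gene (chromosome 10, 80931230 to 80931482), at −log10 p of 11.0 in each edKO library. Next came regions at the gene end of Hoxa4 and over Hoxa3 (chromosome 6, 52191816 to 52192241), inside Zfr2 and inside Flnc, which encodes the muscle filamin. These were followed by regions near Mymk, which encodes a myoblast fusion protein, inside Hdgf, and 7887 bp from Ryr2, the calcium release channel of the cardiac sarcoplasmic reticulum (chromosome 13, 12114832 to 12115173). Regions 3607 bp from Tmem125, inside Sfi1 and 32168 bp from Gm51877, and at the gene end of Rdh11, a retinol dehydrogenase, completed the 10 strongest. Chrm2, the cardiac muscarinic receptor, Zcchc14 and Zmynd8 had 2 each, and every other gene had at most 1, among them 1110032F04Rik and 1700113H08Rik, the first in alphabetical order.

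Among the lists, sarcomere and excitation-contraction genes had 4 edKO-only regions of 110 (Ryr2, Nppb, Kcnj3 and Myl7; odds ratio 3.74, p = 0.0316, adjusted p = 0.253, exact test). Glycolysis genes had 3 of 53 (Ldhb, Hk2 and Pfkl; 6.87, exact p = 0.0206, adjusted p = 0.253) and oxidative phosphorylation genes 2 of 61 (Cox6a2 and Idh2; 5.34, adjusted p = 0.409). Single edKO-only regions were assigned to Tbx5, Ccnd2, Col1a1 and Bnc1, those of Tbx5, Col1a1 and Bnc1 at gene ends. Genes with an edKO-only gene end included Tbx5, Bnc1 and Foxd3. No list passed in this direction.

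Of the edKO-only regions 25.8% lay at gene ends, against 54.2% of all regions called in both edKO hearts, and at like strength no difference was detected (odds ratio 0.881, 0.651 to 1.19, p = 0.450, exact test). In the same exact test this value turned to 1.60 (p = 1.05e-05) with windows around the summits. Without strata it fell to 0.290 (p = 8.10e-19, Fisher's exact test). With 1 library left out it fell to 0.747 without WT 1, to 0.446 without edKO 1 and to 0.518 without edKO 2. The count of 236 was 25 with −log10 p of at least 10 in every list, 1 with that threshold in the edKO hearts only, 670 with lists of equal length and 430 with windows around the summits. Without WT 1, WT 2, edKO 1 and edKO 2 in turn it was 491, 631, 6363 and 2680.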

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

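Among the alternatives, the random lists that take strength into account, the lists without shared members, the strata by region class, the lists without the member with most WT-only regions and the removal of 2 Mb around Rxra and Rxrb were chosen after the results had been seen. Over all alternatives 100 values of the main comparisons stayed on the same side of the threshold or within the range set for them, while 35 moved, 8 lost the threshold, 4 passed it and 1 reversed. The 449 other values of gene lists stayed on the same side of the threshold, many of them with odds ratios that crossed 1 between settings. No paired analysis was possible because the peak lists give presence of a call and no fitted test with a block, and presence in both WT and neither edKO is the same count paired or unpaired. The motif tests and their alternatives were not run for lack of genome sequence, and the gene-end odds ratio of edKO-only regions has no value where only 1 such region was left. In the exact test the odds ratio of the fatty acid list lay between 2.05 and 6.12, with an adjusted p of at most 0.0310, in all alternatives other than no strata (1.51, adjusted p = 0.164) and random lists matched on region number (ratio 1.16, adjusted p = 0.838), apart from the ratio of 1.83 (adjusted p = 0.0288) against random lists with strength. The gene-end odds ratio of WT-only regions lay between 0.163 and 0.530 throughout. Depth limits all counts: a call needs a pileup above the threshold, and edKO 1 had the lowest background level and edKO 2 the lowest enrichment.

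For the other values the cause was not tested, except where fewer libraries or shorter lists by construction change a count. With lists reduced to the length of the shortest there were 2324 WT-only and 670 edKO-only regions, and 150 and 156 such gene ends. With −log10 p of at least 10 in every list there were 25 edKO-only regions, 690 WT-only and 9 edKO-only gene ends, and the Jaccard index was 65.7% within WT, 60.0% within edKO and 53.7% between genotypes. With that threshold in the group only, there were 914 WT-only regions and 1 edKO-only region. With windows around the summits there were 430 edKO-only regions and the gene-end odds ratio of edKO-only regions turned to 1.60, and it was 0.290 without strata. The PPAR and RXR list had an odds ratio of 1.96 without strata and 1.95 without shared members, and ratios of 1.42 and 1.68 against random lists without and with strength. The number of lists past the threshold among WT-only regions, 2 in the main comparison, was 0 without strata, 0 against random lists, 1 against random lists with strength and 1 without shared members.

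Leaving out each heart in turn gave 6941 to 13077 WT-only regions (highest without WT 1), 491 to 6363 edKO-only regions (highest without edKO 1), 589 to 864 WT-only and 84 to 426 edKO-only gene ends. The gene-end odds ratio of edKO-only regions then ran from 0.446 (without edKO 1) to 0.885 (without WT 2), the PPAR and RXR odds ratio from 1.55 (without WT 1) to 2.55 (without edKO 2), the lists past the threshold among WT-only regions from 1 to 2, and those at edKO-only gene ends from 0 to 1 (without edKO 2).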

Other observations

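The depth and enrichment tests, the X chromosome tests, the test against sarcomere regions, those with the 2 Mb window, the random lists with strength, the lists without shared members and the counts of strong regions by list were chosen after the results they bear on had been seen. Of the 35 WT-only regions above the 75th strength percentile, 18 were intergenic, 16 lay over a gene and 1 was at a gene end. Fatty acid and PPAR or RXR target genes (Acaa2, Acot1, Acot2, Angptl4, Cd36 and Pdk4) held 6 of them among 61 strong regions called in both WT hearts (9.84%), against 27 of 8448 (0.320%) for genes of no list and 0 for the other 14 lists, among which the sarcomere list had 58 strong regions. At a share of 0.320% a count of 0 is likely in a list of that size, so it does not set those lists apart from genes of no list. The Acot2 and Acot1 regions, counted singly among the 6, are close neighbours on chromosome 12 (from 83999245 and 84020553). The Angptl4 region lies within 2 Mb of Rxrb. After the 10 strongest, the next 5 lay 7011 bp from Synj2 and inside Serac1 (chromosome 17, 6062777 to 6063153), 32243 bp from Dysf, which encodes the membrane repair protein dysferlin (chromosome 6, 84243303 to 84243867), 8894 bp from Trp53inp2, an autophagy regulator (chromosome 2, 155372517 to 155372917), inside Scn4a, a muscle sodium channel gene (chromosome 11, 106329135 to 106329539), and inside Dglucy (chromosome 12, 100820026 to 100820450).

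More regions were called in both WT hearts alone (5440) than in both edKO hearts alone (236). Lower depth of edKO 2 is argued against by its background level, 1.06 times the WT mean, only as far as that level stands for depth. Its median pileup at a summit was the lowest, at 18 against 23 in each WT library. Lower depth of edKO 1, at 0.838 times the WT mean, and lower enrichment in edKO 2, with a median fold of 7.61 in its 10000 strongest peaks, both remain open and may account for part of the difference. The deletion of both receptors, which the design names, also stays open, since genotype and library quality vary together over 4 hearts.

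Regions near fatty acid and PPAR or RXR target genes were WT-only more often than regions of like strength, though the PPAR and RXR list lost its call without WT 1 (adjusted p = 0.552, exact test), without WT 2 (0.216), without shared members (0.183) and against random lists with strength (0.0672), so the values are for the fatty acid list unless named otherwise. Unequal list length as the whole cause is argued against by an odds ratio of 4.97 with lists of equal length (adjusted p = 3.90e-06, exact test). Cutting the lists does not equalise enrichment, so uneven sensitivity of the libraries stays open. At equal length the mixed pairs with edKO 1 still held 957 and 1105 regions that the remaining pair lacked, and those with edKO 2 460 and 480. A lower share of cardiomyocyte nuclei as the whole cause is argued against by the odds ratio of 2.42 (1.15 to 5.10) against sarcomere regions. This comparison was not repeated under the alternatives. The interval of the sarcomere list itself (0.514 to 1.62) leaves room for some loss, so a part in the excess stays open. Only passenger sequence within 2 Mb of the floxed Rxra and Rxrb is argued against as the cause for the fatty acid list. Without regions in that window its odds ratio was 2.53, against 2.54 with them. That of the PPAR and RXR list was 2.35 without them (adjusted p = 0.0248, exact test). Passenger sequence stays open for the Angptl4 region, which lies in that window. Regions there were WT-only less often than others (36 of 281, odds ratio 0.630, 0.425 to 0.935). Linked sequence beyond 2 Mb was not tested and stays open, as for the Crat region on the chromosome of Rxra. A hypothesis is that part of the WT-only regions near genes of both lists may need RXR in cardiomyocytes to stay open. No test here addressed it, and it rests on a list result that depends on the strength strata (odds ratio 1.51 without them). A change in the metabolic state of the newborn hearts that follows the deletion indirectly was not tested.

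Regions of the X chromosome were frequent among those called in edKO 2 alone, at 159 of 6093 (2.61%), against 54 of 4921 (1.10%) in WT 1, 105 of 7466 (1.41%) in WT 2 and 15 of 2424 (0.619%) in edKO 1. A peak over Xist, the RNA gene that silences 1 X chromosome in females (X, 103460373 to 103483233), was called in edKO 2 alone (103481566 to 103481905, −log10 p 15.7, fold 7.32). These same counts, restated, give an odds ratio of 2.25 (1.81 to 2.80) for X among private regions of edKO 2 against those of the other libraries. Private calls raised in equal proportion on every chromosome would not give this value. A noisier library whose extra calls fall in other proportions was not tested and stays open. That edKO 2 came from a female heart and the others from males may explain both values, but the lists hold 0 peaks on the Y chromosome in any library, so maleness was not shown. The WT-only regions included 76 on X and numbered 5364 without X.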
